A study of Mus musculus with 2 samples.

How the data were processed

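The samples are 2 libraries of sorted mouse B cells, each made on its own BD Rhapsody cartridge, a microwell device in which single cells are captured with barcoded beads. Per the labels, mice were time-stamped on postnatal day 19 with tamoxifen at 50 mg/kg, and CD19+ B cells of a Tom+ and a Tom– fraction were sorted from peritoneal cavity, spleen and Peyer's patches. Tom stands in the transcript list as tdTomato, a red fluorescent reporter. Per the series' design text, Tom+ cells have an early life origin and Tom– cells an adult life origin. Per the labels' protocols, the cells were labelled with a sample multiplexing kit, and the cartridges received 60000 and 50000 viable cells. The labels do not say which cartridge received which number. The panel targeted 463 transcripts, per the labels' protocols. Both cartridges carry the same label and were treated as replicates 1 and 2 of 1 group.

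The authors deposited whole-number counts per cell for transcripts and antibody tags, with no normalisation. The submitters' processing notes name the build mm10. The aligner, its version and whether counts are molecules or reads are not given in the sources used here, so the values are called counts. The deposited tables held 30096 cells with 445 transcripts in cartridge 1 and 22710 cells with 439 transcripts in cartridge 2, with 10 antibody tags in each. The union of the transcripts was 453. Positions come from the GENCODE M21 annotation of GRCm38, in which 448 of the 453 symbols were found by name.

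The tables used here map no cell to a sort fraction, a tissue or a mouse. The comparison of Tom+ with Tom– cells and the comparison of tissues were therefore not run. All comparisons are between classes of cells within the cartridges. The classes may come from different tissues, so a difference between classes cannot be told apart from a difference between tissues.

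Cells with at least 50 transcript counts and at least 20 detected transcripts were kept, which left out 45 and 26 cells. Scrublet (in scanpy 1.11.5) called 0 of 30051 and 0 of 22684 kept cells doublets. A caller that marks no cell among this many has not worked, so doublets remain in the data, and no cell was left out as one.

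Cells were clustered on 72 marker genes found on the panel, which belong to lists for B-1-like, follicular-like, marginal-zone-like, germinal-centre-like, plasma-cell-like, immature-like, memory-like, atypical-like, T-cell-like, NK-like, macrophage-or-monocyte-like, dendritic-like and mast-cell-like cells. Pearson residuals (overdispersion 10, clipped at 10) were computed with a size factor that leaves out the 12 immunoglobulin constant genes. The 20 leading principal components, 15 nearest neighbours, a shared-neighbour graph and Leiden clustering by modularity at resolution 2 with seed 0 gave 34 clusters (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 under Python 3.11.15). A cluster took the name of a list when at least 3 of its 10 leading marker genes came from that list, more than from any other list, and its leading gene was in the list. Leading genes had a log2 fold of at least 0.3 over all other cells, with 20 CPM added to both levels, and were detected in at least 3% of the cluster's cells. In the main clustering no cluster met the rule for immature-like, memory-like, NK-like, macrophage-or-monocyte-like, dendritic-like or mast-cell-like cells. The marker lists, gene lists, tests and alternatives were fixed before the data were examined. The clustering method, its components, neighbours and resolution, and the naming rule were chosen after several clusterings had been looked at, in output that also showed other genes, the antibody tags and the reporter.

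The 381 transcripts outside the marker lists, including the reporter, were held out of the clustering and are the only transcripts tested between classes. For each cartridge and class, counts were summed over cells. Classes of B cells with at least 50 cells in each cartridge entered a single fit with the cartridge as a block. The fit used edgeR 4.0.16 under R 4.3.3, with TMM scaling, filterByExpr, which kept 290 genes, and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method within each contrast and a gene was called at an adjusted p under 0.05. Standard errors (SE) are the size of the log2 fold change divided by the square root of F. Folds per cartridge add 0.5 counts to both sums. The labels do not say that the cartridges hold cells of separate mice. P-values therefore measure the spread between 2 cartridges, which may be technical.

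Named genes were chosen by a rule fixed before the data were examined. From B-1-like against follicular-like cells it takes the 15 largest rises and the 15 largest falls, and from every other contrast 6 and 6, among called genes with a log2 fold change of at least 1 in size, the same direction in both cartridges and at least 50 counts in the higher class in each cartridge. It adds all members of the immunoglobulin constant region and fetal-type lists, up to 4 called members of every other list, and the 5 genes whose share of counts differed most between the cartridges. The other lists are B-cell receptor signalling and co-receptors, chemokine receptors and homing, cytokine receptors and cytokines, Toll-like receptors and adaptors, antigen presentation and co-stimulation, early response genes, NF-kB and survival, interferon response, proliferation and DNA replication, and genes associated with chronic lymphocytic leukaemia (CLL). Lists with at least 4 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way. The interferon and fetal-type lists had too few members for these tests.

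A gene with 0 counts in the lower class is given as a lower bound against a floor of 3 counts over the class. A gene with 1 to 3 counts there is given as a ratio of levels with a 95% counting interval. Shares of cells carry exact Clopper-Pearson 95% intervals, and beside a share of 0 the text gives the limit of 3 counts of the total. Intervals and floors cover counting error only. Near-identical genes, namely Cd1d2 beside the marker Cd1d1, the Iglc genes and the Ighg subclasses, may share reads, and their values are uncertain. For shares of cells with a reporter count, each cell was also thinned to 413 counts, the 20th percentile of counts per cell, and shallower cells were left out. The fit was tested on simulated counts for B-1-like against follicular-like cells. Of 257 simulated genes 200 were changed. All were given a preset dispersion of 0.01, which was not estimated from these data, and genes with few expected counts were left out. The test recovered 92.4% of those changed by a log2 fold of 0.585 and 100% at a log2 fold of 1 and of 2, and it called 8.77% of the unchanged genes. In a contrast with no change it called 0 of 257 genes. These rates hold for that setting only and do not describe genes with few counts or with a wider spread between the cartridges.

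Alternatives fixed in advance were DESeq2 1.42.0 with its size factors, total counts without TMM, library sizes over held-out genes or without immunoglobulin constant genes, no filter on low counts, no block, only the 2 classes compared, leaving out each cartridge, halved and doubled clustering resolution, another seed, a stricter and no cell filter, leaving out the 5% of cells with most counts, clustering on all genes, thinning, and the estimated correlation. An alternative that keeps only cells without a count of 16 T-cell, macrophage or NK genes was chosen after seeing the data. So were the summaries of antibody tags, the sets of 6 T-cell genes, 6 macrophage genes and 5 NK genes, the split of B-1-like cells by their CD5 tag and the split of cells by a reporter count. Antibody tags are given as counts per cell with no normalisation and were not tested. Figures were drawn with matplotlib 3.10.9.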

Results

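Targeted transcripts and 10 antibody tags were counted in sorted mouse B cells on 2 cartridges. The series set B cells of early life origin, marked with a red reporter by tamoxifen after birth, against cells of adult life origin. The tables used here do not tie a cell to a sort fraction or a tissue, so B-cell classes were compared with one another. Differences between classes may in part be differences between the pooled tissues, which cannot be told apart here. The reporter transcript tdTomato was compared between the same classes. Cartridge 1 held 27873346 transcript counts and 162601752 antibody counts, and cartridge 2 held 18604171 and 99888751. A kept cell had a median of 599 transcript counts over 93 transcripts in cartridge 1 and of 554 counts over 89 transcripts in cartridge 2. The 12 immunoglobulin constant genes took 36.4% and 37.98% of the transcript counts. Across the 453 transcripts, which are not independent replicates, Pearson's r between the log levels of the cartridges was 0.997 and Spearman's rho 0.996. Of 347 transcripts with at least 100 counts, 6 differed by more than 2-fold between cartridges. The largest differences in share of counts were those of Igkc (17.7% and 19.5%), Ighm (6.97% and 6.63%), Igha (0.835% and 1.15%), Rps9 (5.19% and 4.88%) and Ighg2b (1.04% and 0.751%).

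B-1-like cells, led by Itgam, Ctla4, Bhlhe41, Spn, Pdcd1lg2 and Cd5, made up 12.98% of cartridge 1 and 12.4% of cartridge 2 (6714 cells). Pdcd1lg2 stands in the memory-like list. A cluster of 1556 cells in this class was named by 4 B-1-like against 3 memory-like markers. Cd5 was counted in 14.1%, 12.5% and 14.4% of the cells of the B-1-like clusters. B-1 cells are innate-like B cells of the body cavities. Follicular-like cells, led by Fcer2a, Bach2, Sell, Il4ra and Ccr7, made up 16.6% and 18.3% (9136 cells). Marginal-zone-like cells with Cd1d1, Cr2, Cd9 and Mzb1 made up 3.51% and 3.71% (1898 cells), and germinal-centre-like cells with Mki67, Top2a, Aicda, Fas and Bcl6 made up 4.32% and 3.57% (2106 cells). Plasma-cell-like cells with Jchain, Prdm1, Tnfrsf17 and Xbp1 were 1.18% and 1.22% (632 cells). Atypical-like cells with Cxcr3, Tbx21 and Itgax were 1.45% and 1.40% (753 cells), and T-cell-like cells with Thy1, Trbc2 and Cd3d were 0.123% and 0.141% (69 cells). The other 19 of 34 clusters met no naming rule and held 59.9% and 59.2% of the cells. Several of these were led by a gene counted in 100% of their cells, such as Bcl6, Lck or Fcer2a. So were follicular-like clusters, with Bach2 or Sell. The follicular-like markers Fcer2a, Il4ra or Sell were among the leading genes of many unnamed clusters. Follicular cells may therefore also lie among the unnamed, which was not tested. Adgre1, a macrophage marker, was also among the leading genes of 2 of the 3 B-1-like clusters and of the atypical-like cluster. Apoe, a gene of the same marker list, was among those of the plasma-cell-like cluster (log2 fold 3.94, in 39.7% of cells). Of the 632 plasma-cell-like cells, 34 (5.38%) held a count of T-cell, macrophage or NK genes. Such a share rises with depth, and the median was 6293 counts per plasma-cell-like and 498 per follicular-like cell. Sorting and the number of mice and tissues pooled can set these shares, so they are not shares of a tissue. The clustering settings and the choice of cells moved them too, to 7.99% for marginal-zone-like, 37.7% for follicular-like, 8.42% for B-1-like, 2.78% for germinal-centre-like, 0.576% for plasma-cell-like and 0.752% or 2.86% for atypical-like cells, a class that another seed did not give.

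**Figure D1:**
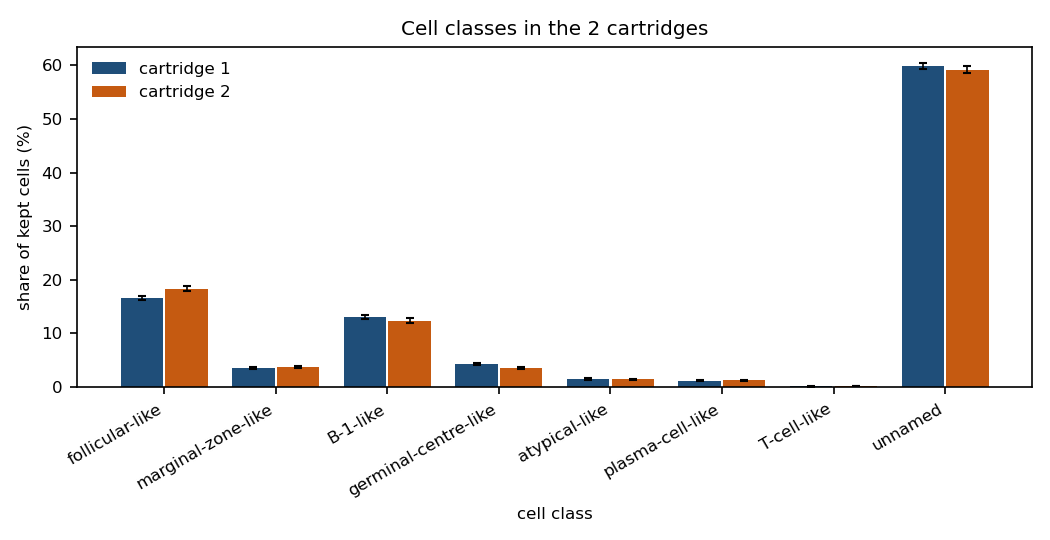
Share of kept cells in each class (%, bars) in cartridge 1 and cartridge 2, with exact 95% binomial intervals as error bars. Follicular-like cells made up 16.6% and 18.3%, B-1-like cells 12.98% and 12.4%, and cells of unnamed clusters 59.9% and 59.2%. Other settings gave up to 37.7% follicular-like and down to 8.42% B-1-like cells.

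The antibody tags, which did not enter the clustering, were set beside the classes as counts per cell (mean of the 2 cartridge medians ± SD). IgM was 5872 on B-1-like and 5133 on marginal-zone-like cells against 783.5 on follicular-like cells. IgD was 1568.5 on follicular-like cells and 343.5 on B-1-like cells. CD1d, a lipid-presenting molecule, was 1060.5 on marginal-zone-like cells, against 137 on B-1-like and 75.5 on follicular-like cells. CD80 was 128 on B-1-like and 3 on follicular-like cells, CD43 was 45 and 9, and CD5 was 104 ± 25.5 and 31. CD19, the B-cell tag of the sort, was 853.5 ± 131 on B-1-like, 357 ± 52.3 on follicular-like and 57 ± 18.4 on germinal-centre-like cells. On T-cell-like cells CD19 was 278.5 ± 162. Cells of unnamed clusters stood at 403.5 for CD19, 902 for IgM and 1353.5 for IgD. The CD23 tag held 118 counts in all, in 0.224% of the cells, and gave no signal on any class. No test was run on the tags.

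**Figure D2:**
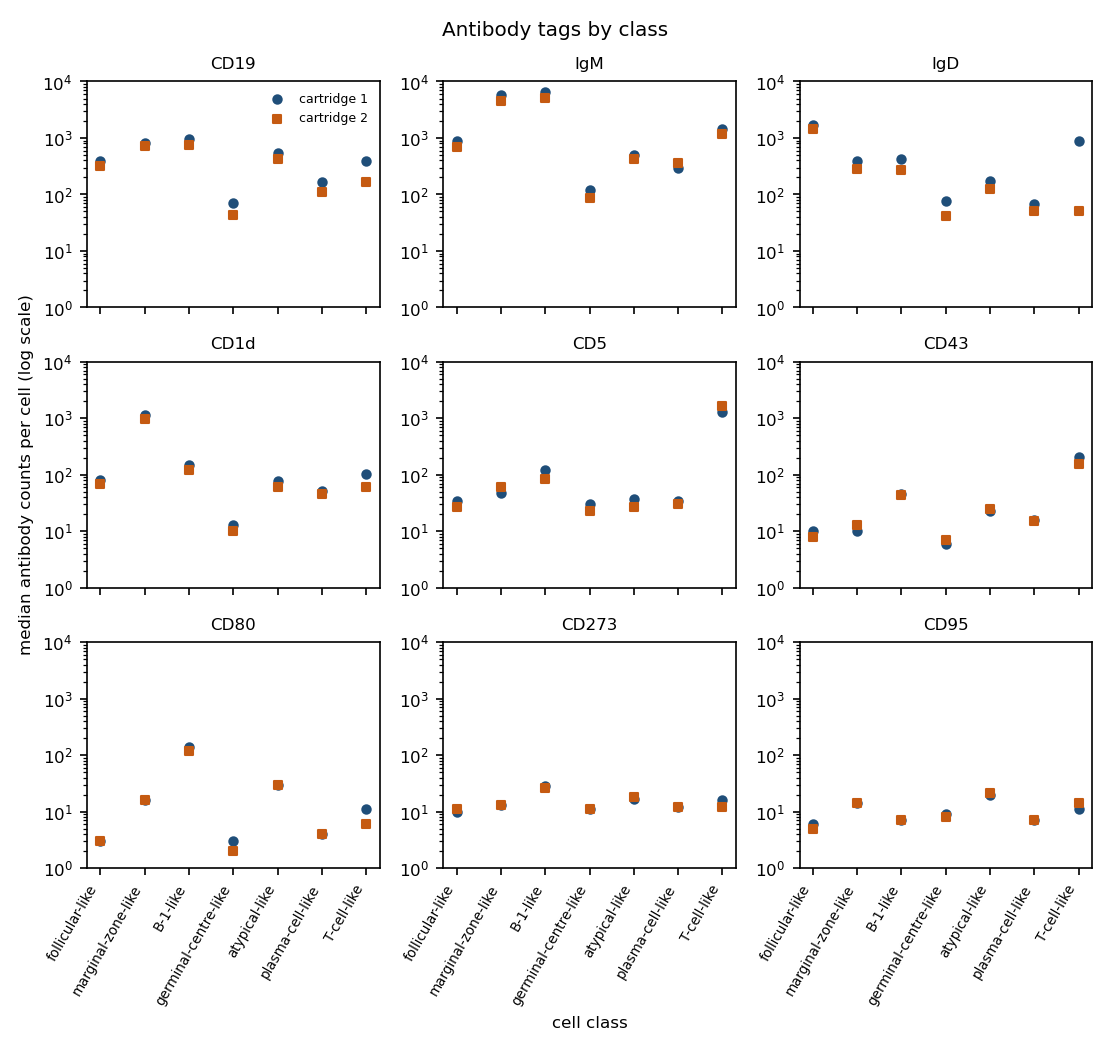
Median antibody counts per cell (log axis) for 9 tags in 7 cell classes, with 1 point for each cartridge and without the CD23 tag, which held 118 counts in all. CD1d was highest on marginal-zone-like cells (1060.5, mean of the cartridge medians), CD80 on B-1-like cells (128) and IgD on follicular-like cells (1568.5), and CD19 was lowest on germinal-centre-like cells (57).

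Among the genes with the largest differences between B-1-like and follicular-like cells were Tnfrsf8, Tnfsf8, Ccl17 and Il18, which were higher, and Lef1, Ighd and Dusp2, which were lower. Tnfrsf8, which encodes CD30, was at 927 ± 77.4 CPM in B-1-like and 75.2 ± 0.0230 CPM in follicular-like cells (SD, n = 2 cartridges), a log2 fold change of 3.62 ± 0.13 (SE). Tnfsf8, which encodes its ligand, was higher by 4.03 ± 0.27, the chemokine gene Ccl17 by 4.23 ± 0.38 and the cytokine gene Il18 by 3.84 ± 0.27. Ccnd2, which encodes cyclin D2, rose from 49.9 ± 0.0244 to 400.3 ± 0.522 CPM (3.0 ± 0.11), and the integrin gene Itgb1 from 259 ± 22.5 to 1873 ± 41.9 CPM (2.85 ± 0.07). The largest falls were those of Lef1, a transcription factor of lymphoid progenitors and T cells (-3.59 ± 0.64), of Ighd (-2.78 ± 0.09, from 30229 ± 378 to 4397 ± 128 CPM) and of the phosphatase gene Dusp2 (-2.60 ± 0.08).

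Other large rises in B-1-like cells were those of Ccr1 (3.38), Ighg3 (3.18), Slc7a7 (2.96), Cd8b1 (2.96), Il15 (2.76) and Mgst1 (2.62). Nrp1 was higher by 3.53, with 2.5 in cartridge 1 and 5.93 in cartridge 2. Il10, an anti-inflammatory cytokine gene, was higher by 3.19 (2.27 and 4.13), and Il2ra by 2.55 (3.23 and 1.94). Ccl9, with 0 counts in follicular-like and 106 in B-1-like cells, was at least 14.0-fold higher against a floor of 3 counts over the class. Of these 106 counts 103 lay in the 199 B-1-like cells that also held a count of T-cell, macrophage or NK genes. Ccr2 had 1 count in follicular-like and 34 in B-1-like cells, a ratio of 13.5 (95% counting interval 2.27 to 549), and 44.1% of the 34 counts lay in such cells. The 6 macrophage genes stood at 96.2 ± 55.3 CPM in B-1-like and 5.26 ± 1.26 CPM in follicular-like cells, and 6 T-cell genes at 17.8 ± 2.58 and 4.05 CPM. Further falls were those of Tgfb3 (-2.44), Cxcr4 (-2.13), Slamf1 (-2.10), Cd72 (-2.05), Trib2 (-2.02), Cd200 (-2.0), Irf7 (-1.93), Stat4 (-1.92), Irf8 (-1.88), Lamp3 (-1.79), Nr4a1 (-1.65), Ccr6 (-1.60) and Dusp1 (-1.56).

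Of the 8 antigen presentation and co-stimulation genes 7 were lower in B-1-like cells and 1 was not past the test. Cd74, the invariant chain of MHC class II, stood at 8997 ± 384 against 21078 ± 1380 CPM (-1.23 ± 0.09, adjusted p = 1.0e-06), H2-Ob fell by 1.26, Cd40 by 0.79 and H2-Ab1 by 0.70. Of 13 B-cell receptor signalling genes 2 were higher and 8 lower, among them the inhibitory co-receptor genes Cd72 (-2.05) and Cd22 (-0.91), Btk (-0.66) and Cd19 (-0.53). Among 12 immunoglobulin constant genes 4 were higher, namely Ighg3, Ighg2b (0.99), Iglc1 (0.71) and Ighm (0.38), and 3 were lower, namely Ighd, Iglc3 (-0.28) and Igkc (-0.19), and Igkc changed direction (0.02) with total counts and no TMM. Ighe (1.96, 3.11 and 0.16 in the cartridges), Igha (1.11, 0.57 and 1.77), Ighg2c (0.30), Iglc2 (0.03) and Ighg1 (-0.09, 0.49 and -0.83) did not pass. Of 9 homing genes 4 were higher and 3 lower, of 11 cytokine and cytokine receptor genes 3 and 5 (Lta -1.47, Tnf -1.31), and of 8 Toll-like receptor genes 3 and 2 (Tlr2 0.75, Tlr7 0.37, Tlr3 -0.43, Tlr1 -1.28). Of 9 early response genes 2 were higher (Myc 1.58) and 6 lower, of 6 NF-kB and survival genes 0 and 4 (Nfkb2 -0.93, Birc3 -0.54, Nfkb1 -0.24, Bcl2 -0.21), and of 3 interferon genes 0 and 2 (Irf7, Stat1 -0.89). Among 4 proliferation genes Ube2c (1.46) and Tyms (1.07) were higher and Pcna (-0.27) lower. Both fetal-type genes passed in opposite directions, with Arid3a at 0.73 and Igf2bp3 at -2.40. Of 6 genes associated with CLL 3 were higher and 3 lower.

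With edgeR's quasi-likelihood test 94 of 290 genes were higher and 110 lower at an adjusted p under 0.05, and 47 and 38 of these had a log2 fold change of at least 1 in size. Counts adjusted over the list alone were the same, except for proliferation with 2 higher and 2 lower. No list passed camera (antigen presentation, adjusted p = 0.066, and 0.73 with an estimated correlation). The median gene was at -0.08, and DESeq2 size factors raised the median by 0.13, library sizes over held-out genes by 0.12 and total counts without TMM by 0.20, which gave 121 higher and 78 lower genes. A scaling moves all genes of a contrast by about the same amount, so fold changes stand relative to the median gene, and the direction of a gene near the median depends on the scaling. Homing changed to 5 higher and 2 lower with Icam1 turned, and NF-kB to 2 and 2, under total counts without TMM.

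**Figure D3:**
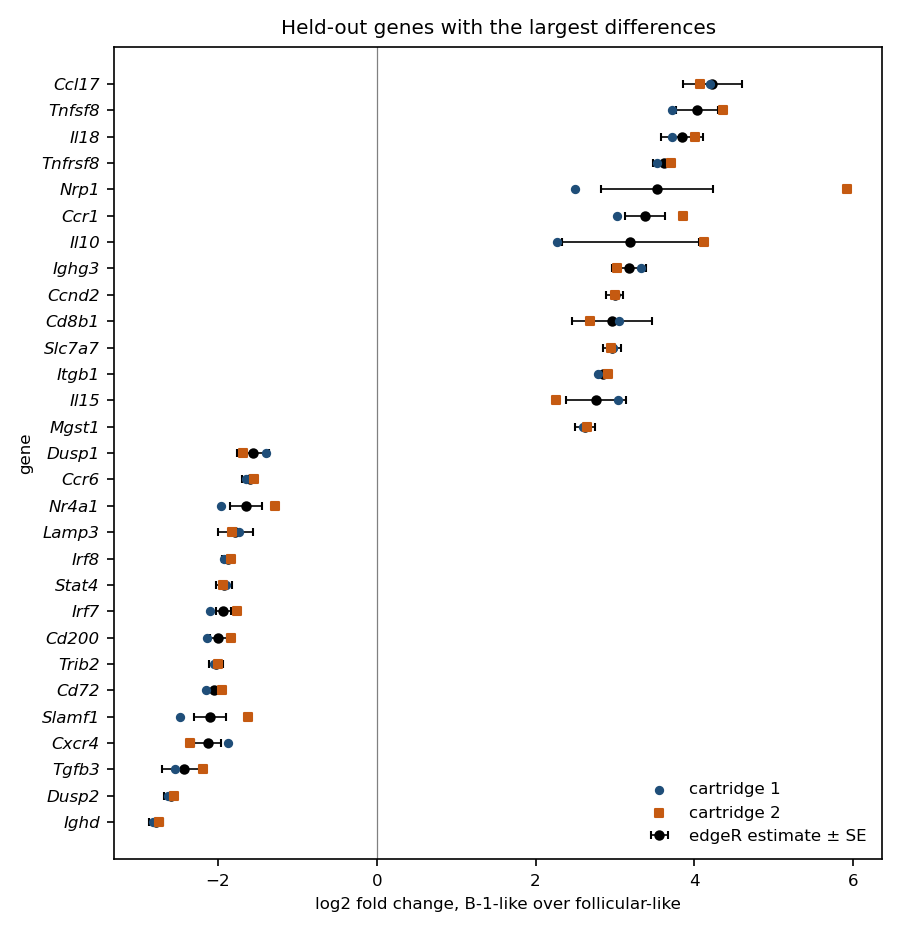
Log2 fold changes of B-1-like over follicular-like cells for held-out genes with large differences and at least 4 counts in the lower class, as the edgeR estimate ± SE and as the fold within each cartridge. Ccnd2 was at 3.0 in both cartridges, and Nrp1 was at 2.5 and 5.93.

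Positions are given for GRCm38 with GENCODE M21. Ccnd2 lies on chromosome 6 from 127125162 to 127152193 and Igf2bp3 on the same chromosome from 49085223 to 49214957. Itgb1 (128685654 to 128733200), Ccl17 (94810453 to 94812036) and Tlr3 (45395665 to 45411080) lie on chromosome 8, and Tnfrsf8 (145267137 to 145315164) and Tnfsf8 (63831308 to 63861347) on chromosome 4. The constant genes Ighd (113406604 to 113416324), Ighg3 (113356224 to 113361232) and Igha (113254830 to 113260236) lie on chromosome 12. Lef1 lies on chromosome 3 from 131110471 to 131224356, Arid3a on chromosome 10 from 79927043 to 79955018 and Ube2c on chromosome 2 from 164769898 to 164778822. The panel counts say nothing of which part of a gene was read.

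Marginal-zone-like cells, whose counterparts in the spleen respond early to blood-borne antigen, were compared with follicular-like cells. Tlr3, a receptor for double-stranded RNA, stood at 524 ± 31.7 against 29.2 ± 2.30 CPM (log2 fold change 4.16 ± 0.12, SE). Higher levels were also found for Trem1 (4.35 ± 0.42), the kinase gene Zap70 (3.65 ± 0.29), the inhibitory receptor gene Lilrb4a (3.63 ± 0.21) and the scavenger receptor gene Cd36 (2.86 ± 0.15). Csf2, the gene of the growth factor GM-CSF, had 0 counts in follicular-like and 43 in marginal-zone-like cells and was at least 37.5-fold higher. Cd1d2 was higher by 7.36 ± 0.37, a value that is uncertain because Cd1d2 is a near copy of the marker Cd1d1. The largest falls were those of Fosb (-3.41 ± 0.31), Cxcr4 (-3.25 ± 0.20, with -2.74 and -3.86 in the cartridges), Trib2 (-3.20 ± 0.12), the activation marker Cd69 (-3.20 ± 0.21) and Lmna (-3.15 ± 0.33, with -2.36 and -4.13). Lef1 had 3 counts in marginal-zone-like and 109 in follicular-like cells, a follicular-like level 13.9 times as high (95% counting interval 4.62 to 68.3).

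Of 8 Toll-like receptor genes 6 were higher in marginal-zone-like cells and 0 lower, among them Tlr7 (1.37 ± 0.09), Tlr4 (0.57) and Ly86 (0.51). The list passed camera (adjusted p = 0.0093, and adjusted p = 0.24 with an estimated correlation). Of 13 B-cell receptor signalling genes 6 were higher, among them Cd81 (0.86), the kinase gene Blk (0.79), Blnk (0.71) and Siglecg (0.50), and 3 were lower. Of 9 homing genes 2 were higher and 5 lower, among them Itgb7 (-2.52 ± 0.09), Ccr6 (-1.01) and Cd44 (-0.84). Among 12 immunoglobulin constant genes Ighg3 was higher (1.95 ± 0.21), and Ighd (-2.52 ± 0.09) and Igkc (-0.62) were lower. The other 9 did not pass, among them Ighm (0.08), Ighg2b (0.20), Iglc1 (0.13), Igha (0.01), Iglc2 (-0.01), Iglc3 (-0.15), Ighg1 (-0.46) and Ighg2c (-0.93, with -2.10 and 0.24), and Iglc2 had the opposite sign with DESeq2 (0.15). Ighg3 took 0.0498% of the counts of marginal-zone-like, 0.0115% of follicular-like and 0.0649% of T-cell-like cells. A level this low was thus also found in the T-cell-like class, and its source was not tested. Of 11 cytokine genes 3 were higher and 5 lower, among them Il2ra (-2.13, with -1.29 and -2.85), Il12a (-2.02) and Il6ra (-1.93). Of 6 CLL genes 2 were higher and 4 lower, among them Cd200 (-2.50). Of 8 antigen presentation genes 2 were higher (Cd86 0.76, Cd40 0.74) and 3 lower (H2-Ob -1.12, Cd74 -0.76). Of 9 early response genes 1 was higher (Myc 1.31) and 5 lower (Nr4a1 -1.94, Egr1 -1.74), and of 6 NF-kB and survival genes 0 were higher and 5 lower (Mcl1 -0.56, Birc3 -0.52, Bcl2 -0.46, Nfkb2 -0.29). Irf7 (-0.83), Tyms (1.12) and Pcna (-0.52) passed among the interferon and proliferation genes, the fetal-type Arid3a did not (0.31), and Igf2bp3 had 3 counts.

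The edgeR test called 64 genes higher and 92 lower, 25 and 36 of them by at least 1 in log2. DESeq2 size factors, which raised the median of all genes by 0.17, gave 98 higher and 69 lower, and total counts without TMM, which raised it by 0.16, gave 99 and 69. Adjusted over the list alone, the cytokine list had 4 higher and 5 lower, antigen presentation 2 and 4, and proliferation 1 and 2, and the other lists were the same.

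Germinal-centre-like cells, the class of dividing cells that mutate and switch their antibody genes, were named from the cell-cycle markers Mki67 and Top2a among others, so higher levels of other cell-cycle genes are part of how the class was found. The mitotic ubiquitin-conjugating enzyme gene Ube2c stood at 1989 ± 24.7 against 7.03 ± 0.856 CPM in follicular-like cells (log2 fold change 8.12 ± 0.37, SE). Higher levels were also found for 2810417H13Rik (7.42 ± 0.33), the actin-bundling gene Fscn1 (5.81 ± 0.20), the nucleotide synthesis gene Tyms (5.44 ± 0.14) and the adenosine deaminase gene Ada (5.06 ± 0.12). Havcr1, which encodes TIM-1, stood at 873 ± 13.2 against 18.0 ± 1.32 CPM (5.60 ± 0.12). The largest falls were those of Ighd (-3.05 ± 0.09), Stat4 (-2.90 ± 0.12), Pik3ip1, an inhibitor of PI3 kinase (-2.50 ± 0.09), Nod1 (-2.42 ± 0.10), Fosb (-2.42) and Arl4c (-2.38, with -2.98 and -1.62 in the cartridges).

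All 4 proliferation genes were higher in germinal-centre-like cells, with Mcm4 at 2.67 ± 0.08 and Pcna at 2.34 ± 0.11 (camera adjusted p = 0.0087, and adjusted p = 0.47 with an estimated correlation). Both fetal-type genes were higher, Igf2bp3 by 3.70 (4.59 and 2.49 in the cartridges) and Arid3a by 1.25 ± 0.11. Of 13 B-cell receptor signalling genes 1 was higher and 11 lower, among them Cd72 (-1.26), Blk (-0.90), Cd37 (-0.84) and Cd79a (-0.82), and total counts without TMM gave 2 and 8 with Cd81 turned (camera adjusted p = 0.014, and adjusted p = 0.98 with an estimated correlation). Of 12 immunoglobulin constant genes 6 were higher and 5 lower. The higher ones were Ighg1 (4.77), Igha (4.71, with 4.06 and 5.45), Ighe (4.46), Ighg2b (3.06), Ighg2c (1.39, with 0.55 and 2.28) and Ighg3 (1.29), and the lower ones Ighd, Ighm (-1.79 ± 0.08), Iglc2 (-0.91), Iglc3 (-0.65) and Igkc (-0.61), with Iglc1 at 0.10 not past the test. Igha took 1.89 ± 0.124% of the transcript counts of germinal-centre-like cells and 0.0564% of those of follicular-like cells.

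Further lists differed member by member between germinal-centre-like and follicular-like cells. Of 8 antigen presentation genes Cd86 (1.02) and 1 other were higher and 6 lower, among them Cd74 (-1.37 ± 0.09), H2-Aa (-0.77) and H2-Ob (-0.71), and total counts without TMM gave 2 and 3 with H2-Ab1 and H2-DMa turned. Of 8 Toll-like receptor genes 1 was higher and 5 lower, among them Tlr2 (-1.68), Tlr7 (-1.54), Tlr4 (-1.33) and Tlr1 (-1.08). Of 6 NF-kB and survival genes Bcl2a1a was higher (1.40) and 5 were lower, among them the anti-apoptotic gene Bcl2 (-2.10 ± 0.10), Birc3 (-0.76) and Mcl1 (-0.72). Of 9 homing genes 3 were higher, among them Icam1 (1.39 ± 0.06), and 4 lower, among them Itgb7 (-2.28) and Ccr6 (-1.43). Ccr10 had 2 counts in follicular-like and 14 in germinal-centre-like cells, a ratio of 13.3 (95% counting interval 3.05 to 120). Its log2 folds within the cartridges were 2.34 and 4.78. Of 11 cytokine genes 4 were higher (Il10 4.14, Tnf 1.36) and 4 lower (Il6ra -2.04, Il12a -1.59), of 9 early response genes 3 (Egr1 1.62, Myc 0.47) and 4 (Cd69 -2.13, Nr4a1 -1.48), and of 6 CLL genes 2 (Ccnd2 0.75) and 2 (Cd200 -1.30). Irf7 was the lower gene of 3 interferon genes (-0.42, and 0.01 with total counts and no TMM).

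In edgeR, 92 genes were higher and 121 lower in germinal-centre-like cells, 65 and 55 of them by at least 1 in log2. Total counts without TMM raised the median by 0.43 and gave 121 higher and 88 lower, DESeq2 raised it by 0.21 (100 and 103) and library sizes over held-out genes by 0.20 (102 and 107). The counts adjusted over the list alone were the same for every list.

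Immunoglobulin constant genes took 86.3 ± 1.02% of the transcript counts of plasma-cell-like cells, with 85.6% and 87.1% in the cartridges, against 32.7% and 33.7% in follicular-like cells. Igkc alone took 54.5 ± 3.12% against 16.03 ± 0.888%, Ighg2b 8.68 ± 2.80% against 0.0396%, and Igha 7.67 ± 1.98% against 0.0564%. Ighm took 0.892 ± 0.0297% against 6.81%. After TMM scaling, 9 of the 12 genes were higher, from Iglc3 (2.14 ± 0.10) to Ighg2b (10.18 ± 0.42), Ighd (-3.38 ± 0.09) and Ighm (-0.51) were lower and Ighe did not pass (2.82, with 4.24 and -3.35 in the cartridges), and total counts without TMM gave 8 and 3 with Iglc3 turned (camera adjusted p = 0.0058, and adjusted p = 0.18 with an estimated correlation). The others that rose were Ighg1 (10.04), Igha (9.61, with 8.67 and 10.54), Ighg3 (9.48), Ighg2c (9.19), Igkc (4.19), Iglc1 (4.12) and Iglc2 (2.70). Tigit, an inhibitory receptor gene, had 2 counts in follicular-like and 299 in plasma-cell-like cells, a ratio of 982 (95% counting interval 270 to 8149). Its log2 folds within the cartridges were 10.57 and 8.47. Ccr10, a receptor for mucosal chemokines, had 2 and 132 counts, a ratio of 434 (118 to 3618). Within the cartridges its log2 folds were 7.16 and 9.82. Il10 was higher by 7.24 (5.52 and 8.65), and Pax5, the B-cell identity factor, was lower by 2.65 on the log2 scale (-2.65 ± 0.13).

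All 8 antigen presentation genes were lower in plasma-cell-like cells, with Cd74 at -1.84 ± 0.09, Cd40 at -1.77, H2-DMa at -1.33 and H2-Aa at -1.24 (camera adjusted p = 0.0058, and adjusted p = 0.48 with an estimated correlation). Of 13 B-cell receptor signalling genes 10 were lower, among them Cd72 (-2.37), Cd37 (-2.02), Cd22 (-2.01) and Siglecg (-1.58), and 2 higher, and without TMM 13 were lower with Cd79a and Cd81 turned (camera adjusted p = 0.0070, and adjusted p = 0.48 with an estimated correlation). All 6 NF-kB and survival genes were lower, among them Birc3 (-1.43), Nfkb2 (-1.39), Bcl2 (-1.36) and Nfkb1 (-1.16), though Mcl1 turned with DESeq2 (camera adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation). Of 8 Toll-like receptor genes 6 were lower and 0 higher, among them Tlr1 (-2.55), Tlr9 (-1.44), Ly86 (-1.36) and Tlr3 (-1.30), and DESeq2 left 4 lower with Myd88 turned. Of 9 homing genes 3 were higher (Itgb1 1.17) and 4 lower (Cxcr4 -1.90, Itgb7 -1.25), with Itga4 turned under DESeq2 and Itgb1 and Cd44 under total counts without TMM. Cytokine genes had 3 higher (Il2ra 2.79, with 3.44 and 2.20) and 6 lower (Il12a -2.42, Lta -2.10) of 11, with Tnfrsf13b turned without TMM. Early response genes had 2 higher (Egr1 2.81, Jun 2.02) and 4 lower (Cd69 -1.86, Nr4a1 -1.76, with -2.56 and -1.03) of 9, with Jun turned without TMM. Ifitm3 (2.24, with 1.64 and 2.71) and Irf7 (0.49) were higher and Stat1 lower (-0.74), and without TMM both higher ones turned. Ube2c was higher by 5.92 (4.95 and 6.70), Tyms by 3.24 and Arid3a by 2.61 ± 0.11. Of 6 CLL genes 1 was higher (Ccnd2 2.12) and 2 lower (Cd200 -2.54), and Ccnd2 turned without TMM. Igf2bp3 did not pass (1.19, with 1.78 and 0.60). Lamp3 was lower (-3.07, with -2.68 and -3.88).

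For plasma-cell-like cells edgeR called 98 genes higher and 115 lower, 73 and 67 of them by at least 1 in log2. The scaling decides some of these directions. Total counts without TMM moved the median by -2.42 and gave 34 higher and 212 lower genes, with 49 of 213 called genes turned. DESeq2 moved it by 0.24 (110 and 102, with 3 called genes turned) and library sizes over held-out genes by 0.10 (0 turned). Adjusted over the list alone, homing had 3 higher and 5 lower, and the other lists were the same.

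Atypical-like cells, a T-bet-expressing B-cell class, had higher levels of Fscn1 (log2 fold change 4.55 ± 0.24, SE) and of the integrin gene Itgb1, which stood at 1256 ± 41.6 against 259 CPM (2.27 ± 0.07). Of 12 immunoglobulin constant genes 6 were higher, namely Ighe (4.93 ± 0.94), Ighg2c (4.62, with 4.06 and 5.22 in the cartridges), Ighg2b (3.81 ± 0.32), Igha (3.07, with 2.56 and 3.71), Ighg3 (2.91 ± 0.22) and Iglc1 (0.66), and 5 were lower, namely Ighd (-2.81 ± 0.09), Ighm (-0.74), Iglc3 (-0.47), Iglc2 (-0.41) and Igkc (-0.34), of which Igkc turned (0.07) with total counts and no TMM. Ighg1 did not pass (0.52). Large rises with counts in cells of mixed type were those of Ccl5 (8.27 ± 0.34, with 9.56 and 7.61), Il2rb (4.63 ± 0.35, with 3.92 and 5.77) and Fcer1g (4.58 ± 0.31). In the 22 of 753 atypical-like cells with a count of T-cell, macrophage or NK genes lay 729 of the 736 Ccl5 counts, 39.2% of the Il2rb counts and 50.5% of the Fcer1g counts. Without these cells Il2rb was higher by 3.94 and Fcer1g by 3.73. Ccr2 had 1 count in follicular-like and 15 in atypical-like cells, all in those 22 cells, a ratio of 62.2 (95% counting interval 9.58 to 2620). The 5 NK genes stood at 987 ± 601 CPM in atypical-like and 1.89 CPM in follicular-like cells.

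All 13 B-cell receptor signalling genes were lower in atypical-like cells, among them Cd37 (-0.77), Siglecg (-0.77), Btk (-0.74) and Cd79b (-0.71), with a median of -0.49 (camera adjusted p = 0.022, and adjusted p = 0.65 with an estimated correlation). Total counts without TMM gave 1 higher and 4 lower with Cd22, Cd72, Cd81, Lyn and Syk turned, and DESeq2 10 lower with Cd81 turned. Of 8 antigen presentation genes Cd86 was higher (0.67) and 7 lower, among them Cd74 (-1.19 ± 0.09), H2-Ob (-0.84) and Cd40 (-0.74). Of 9 homing genes 5 were higher, among them Cd44 (0.82) and Ccr2, and 2 lower, among them Cxcr4 (-1.73 ± 0.18), and without TMM 7 were higher with Itgb7 turned. Of 11 cytokine genes 0 were higher and 3 lower, namely Il12a (-1.75), Tnfrsf13c (-0.54) and Ltb (-0.48). Of 6 CLL genes 1 was higher (Ccnd2 1.78) and 2 lower (Cd200 -1.09). Of 8 Toll-like receptor genes Tlr3 was higher (0.78) and 3 were lower (Tlr4 -0.95, Tlr1 -0.79, Myd88 -0.20), and without TMM 6 were higher with Myd88 turned. The early response genes had 0 higher and 4 lower, namely Nr4a1 (-2.57, with -3.27 and -1.87), Dusp2 (-1.59), Cd69 (-0.99) and Fosb (-0.74). Bcl2a1a was higher (0.66) and 5 other NF-kB and survival genes lower (Nfkb2 -0.97, Birc3 -0.92, Bcl2 -0.63). Irf7 (-1.61), Oas2 (-1.76), Lamp3 (-1.80), Stat1 (-0.54) and Pcna (-0.43) were lower, and Ube2c (3.28), Tyms (1.71) and Arid3a (0.87) higher. Igf2bp3 was at 0.24 and did not pass.

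The edgeR counts for atypical-like cells were 73 higher and 117 lower, 50 and 18 of them by at least 1 in log2. DESeq2 raised the median by 0.19 and gave 83 and 88, library sizes over held-out genes raised it by 0.17 and gave 88 and 91, and total counts without TMM raised it by 0.41 and gave 121 and 47. Adjusted over the list alone, homing had 6 higher and 2 lower, and the other lists were the same.

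**Figure D4:**
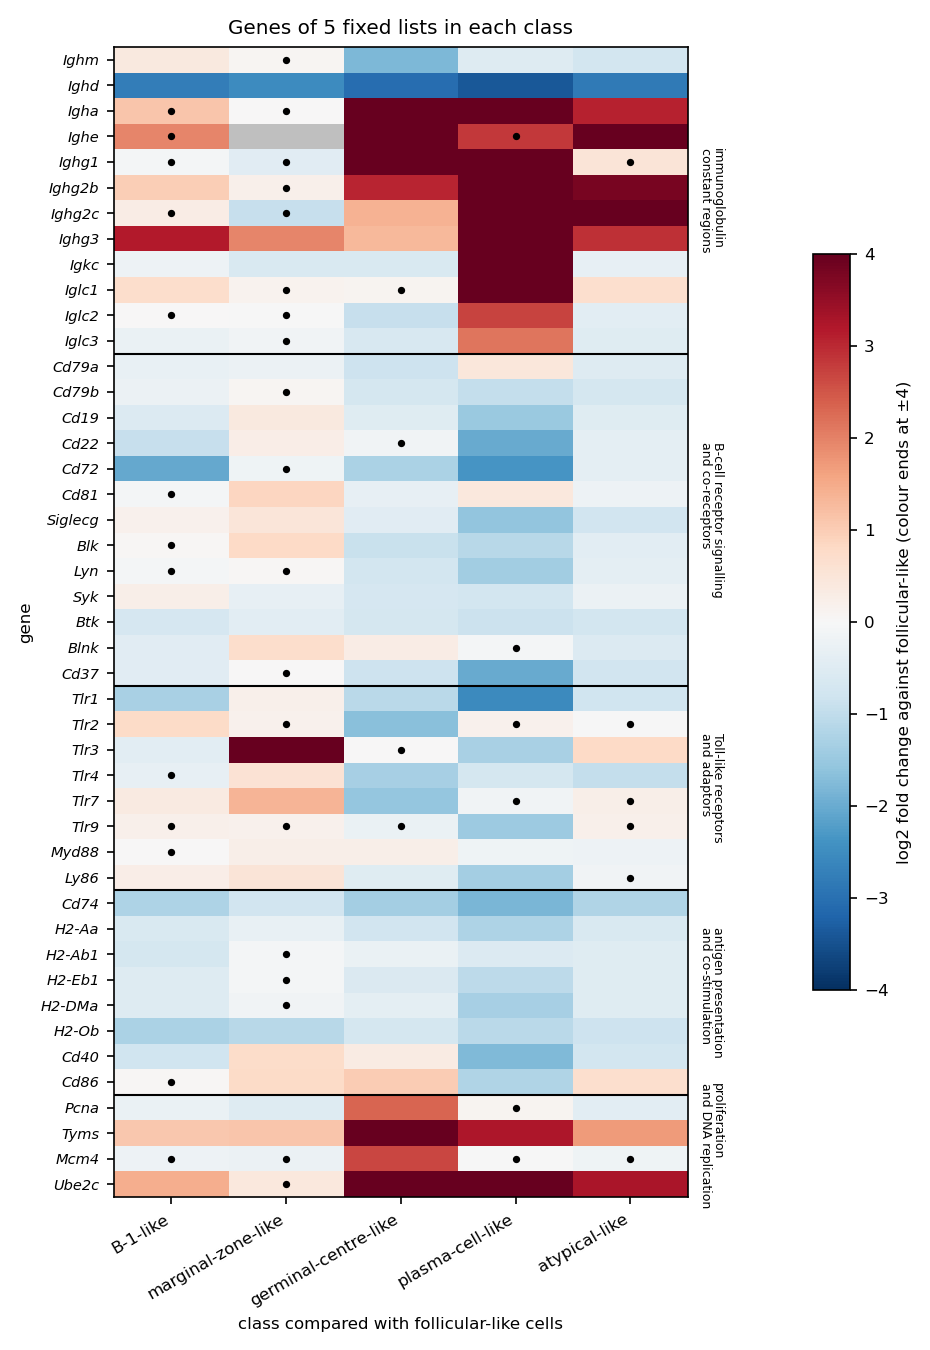
Log2 fold changes against follicular-like cells (colour, ends at ±4) for the genes of 5 fixed lists in 5 classes, with a dot on genes not past the edgeR test and grey where a class had at most 3 counts. Ighd was lower in all 5 classes, from -2.52 to -3.38. All 13 B-cell receptor signalling genes were lower in atypical-like cells, where 5 of them turn with total counts and no TMM.

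B-1-like and marginal-zone-like cells were compared directly, since both are innate-like classes with high IgM. Ccnd2 stood at 400.3 ± 0.522 CPM in B-1-like and 35.4 ± 3.78 CPM in marginal-zone-like cells (log2 fold change 3.47 ± 0.13, SE). Tnfsf8 was higher in B-1-like cells by 5.08 ± 0.40, Il2ra by 4.68 ± 0.47, Lgals3, which encodes galectin-3, by 4.43 ± 0.13 and Tnfrsf8 by 4.31 ± 0.16. Ccl17 had 1 count in marginal-zone-like and 562 in B-1-like cells, a ratio of 85.3 (95% counting interval 15.3 to 3376). Il10 had 1 and 118, a ratio of 17.9 (3.15 to 713). Within the cartridges the log2 folds were 7.23 and 5.21 for Ccl17 and 2.85 and 5.63 for Il10. Ccl9 was at least 5.36-fold higher, with 103 of its 106 counts in the 199 B-1-like cells that held counts of other cell types. The genes higher in marginal-zone-like cells were led by Csf2 (-5.65 ± 0.73, with -4.92 and -5.61), Trem1 (-5.07 ± 0.40), Tlr3 (-4.59 ± 0.12), Zap70 (-2.84 ± 0.25) and Dusp2 (-2.77 ± 0.08), beside the near copy Cd1d2 (-5.94).

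Of 13 B-cell receptor signalling genes 11 were lower in B-1-like than in marginal-zone-like cells and 1 higher, among them Cd72 (-1.88), Cd22 (-1.18), Blnk (-1.17) and Cd81 (-0.94) (camera adjusted p = 0.0049, and adjusted p = 0.43 with an estimated correlation). Of 8 antigen presentation genes 7 were lower, among them Cd40 (-1.53 ± 0.10), Cd86 (-0.70), H2-Ab1 (-0.63) and Cd74 (-0.47) (camera adjusted p = 0.020, and adjusted p = 0.43 with an estimated correlation). Of 8 Toll-like receptor genes 6 were lower, among them Tlr1 (-1.49), Tlr7 (-0.99) and Tlr4 (-0.91), and 1 higher. Of 9 homing genes 5 were higher (Itgb7 3.11, Itgb1 2.13, Cd44 1.79, Cxcr4 1.11) and 2 lower, and of 11 cytokine genes 4 were higher (Il6ra 2.39) and 6 lower (Lta -2.16). Of 9 early response genes 4 were higher, among them Fosb (3.05), Cd69 (1.85) and Jun (1.39), and 2 lower. Immunoglobulin constant genes had 5 higher, namely Ighg3 (1.23), Ighg2b (0.79), Iglc1 (0.58), Igkc (0.43) and Ighm (0.30), and Ighd lower (-0.26). Ighe, Igha (1.10, with 0.41 and 2.15), Ighg2c (1.23, with 2.56 and -0.26), Ighg1 (0.37), Iglc2 (0.04) and Iglc3 (-0.13) did not pass. Of 6 NF-kB and survival genes 2 were higher (Mcl1 0.68, Bcl2 0.25) and 1 lower (Nfkb2 -0.65), and of 6 CLL genes 3 were higher (Cd200 0.51) and 1 lower. Arid3a was higher (0.42), Igf2bp3 did not pass (-1.57, with -1.99 and -0.50), no proliferation gene passed, and Irf7 (-1.10) and Stat1 (-0.93) were lower. Ifitm3 was higher by 2.02 (1.44 and 6.17), with 59.6% of its counts in cells that held counts of other cell types, and stood at 0.73 without them (adjusted p = 0.44).

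In edgeR, 81 genes were higher in B-1-like and 93 in marginal-zone-like cells, 50 and 29 of them by at least 1 in log2. Library sizes without immunoglobulin constant genes moved the median by -0.13. Adjusted over the list alone, early response genes had 6 higher and 2 lower and CLL genes 4 and 1, and the other lists were the same. Over the 60 list tests of the 6 contrasts, 14 had a median, mean, camera and fry direction that were not all of 1 sign, which concerned none of the 10 camera calls. They were the immunoglobulin list in B-1-like, germinal-centre-like and atypical-like cells against follicular-like cells, the cytokine list in all contrasts but that of atypical-like cells, the Toll-like list in B-1-like cells, the CLL list in B-1-like and atypical-like cells, the proliferation list in marginal-zone-like cells and the homing list in germinal-centre-like and plasma-cell-like cells. None of the 10 camera calls held with an estimated correlation, and fry called 47 of the 60.

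The reporter transcript tdTomato was counted in 2307 of 52735 cells. Tom+ and Tom– cells were sorted and loaded together, so the sort can set the reporter shares, which are not shares of a class in the mouse. A count was found in 10.5 ± 0.692% of germinal-centre-like cells (SD, n = 2 cartridges), 9.11 ± 1.58% of B-1-like, 7.09 ± 0.329% of plasma-cell-like, 5.60 ± 0.523% of marginal-zone-like, 4.19 ± 0.583% of atypical-like and 2.18 ± 0.668% of follicular-like cells. Of 69 T-cell-like cells, which a CD19 sort should lack and whose reporter state is not known, 1 held a count. Median depth per cell was 737.5 counts in germinal-centre-like, 1390 in B-1-like, 498 in follicular-like and 827 in T-cell-like cells. With each cell thinned to 413 counts the shares were 4.78 ± 1.24% in germinal-centre-like, 2.28 ± 0.0225% in B-1-like, 2.37 ± 0.339% in marginal-zone-like, 1.93 ± 0.0730% in plasma-cell-like, 2.23 ± 0.349% in atypical-like and 1.71 ± 0.118% in follicular-like cells. In T-cell-like cells the thinned share was 0 of 54 cells, which allows up to 5.56% at 3 counts of the total. Thinning left out 2352 follicular-like, 335 B-1-like and 532 germinal-centre-like cells. It fixes the number of all transcript counts, those of immunoglobulin constant genes included. These genes took 86.3% of the counts in plasma-cell-like, 33.2% in follicular-like and 26.1% in germinal-centre-like cells. Far fewer other counts are thus left in a thinned plasma-cell-like cell, which lowers the share of that class.

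As a share of all transcript counts, tdTomato stood at 125 ± 26.1 CPM in germinal-centre-like, 61.0 in B-1-like and 62.9 in marginal-zone-like cells. It stood at 39.7 ± 10.2 CPM in follicular-like, 35.5 in atypical-like and 12.4 in plasma-cell-like cells. The plasma-cell-like level is lowered by the immunoglobulin counts in the total. Against follicular-like cells, edgeR gave tdTomato a log2 fold change of 1.17 ± 0.22 in germinal-centre-like cells (adjusted p = 6.6e-04), with 0.71 in cartridge 1 and 1.74 in cartridge 2. It did not pass in B-1-like (0.40 ± 0.20, adjusted p = 0.105), marginal-zone-like (0.48 ± 0.24, adjusted p = 0.128) or atypical-like cells (-0.58 ± 0.32, adjusted p = 0.133), though total counts without TMM called it in B-1-like (0.60) and marginal-zone-like cells (0.64). In plasma-cell-like cells it passed at 0.72 ± 0.29 (adjusted p = 0.047), with 0.43 in cartridge 1 and 1.10 in cartridge 2. This call was lost under 4 other settings (adjusted p = 0.0749 to 0.136), and the direction turned to -1.68 with total counts and no TMM. B-1-like and marginal-zone-like cells differed by -0.08 (adjusted p = 0.766).

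**Figure D5:**
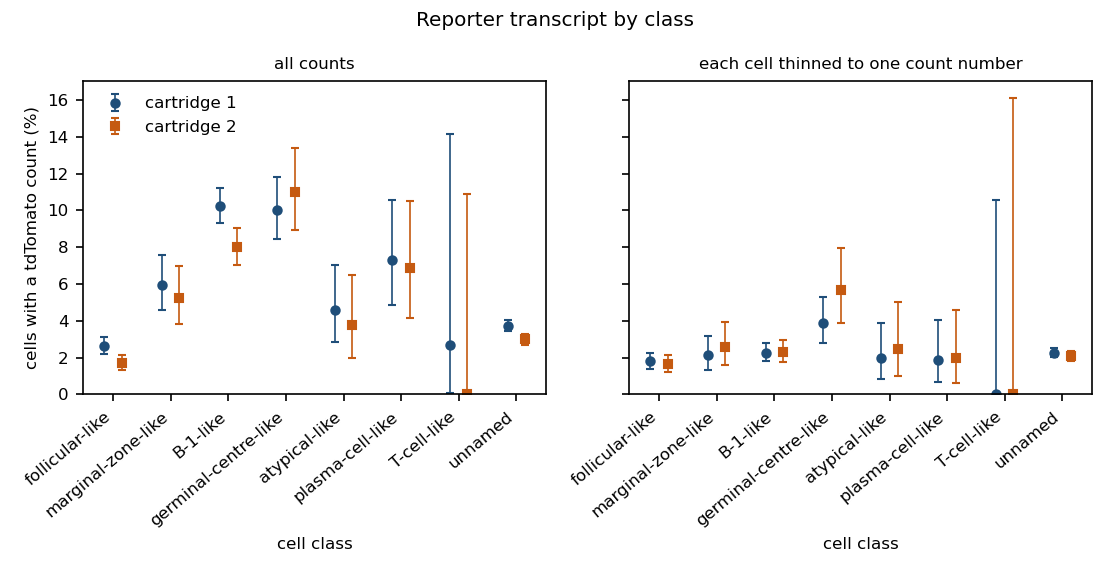
Share of cells with a tdTomato count (%, with exact 95% binomial intervals) by class and cartridge, with all counts and with each cell thinned to 413 counts. With all counts the share was 10.5% in germinal-centre-like and 2.18% in follicular-like cells, and after thinning 4.78% and 1.71% (means of the cartridges).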

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

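The tests of antibody counts and the comparisons of interval bounds for the reporter in germinal-centre-like cells were chosen after the results were seen, while the contrasts between classes, the thinning and the scalings were fixed before the data were examined.

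Igf2bp3, a fetal-type RNA-binding protein gene, was called lower in B-1-like than in follicular-like cells (-2.40) and higher in germinal-centre-like cells (3.70), and the test of the difference between the classes gave -6.10 ± 0.66 (edgeR, adjusted p = 1.07e-05). It rests on few counts, with 6 in B-1-like, 106 in germinal-centre-like (84 and 22 in the cartridges) and 14 in follicular-like cells. Ccnd2 went the other way in the innate-like classes, with 3.0 in B-1-like and -0.47 in marginal-zone-like cells against follicular-like cells (adjusted p = 0.038 for the latter), and the tested difference was 3.47 ± 0.13. CD19 antibody counts on the 69 T-cell-like cells had a mean of the cartridge medians of 278.5, beside 357 on follicular-like and 57 on germinal-centre-like cells. B-cell transcripts were present there too, with Cd79a at 8733 ± 2653 CPM in T-cell-like and 15186 CPM in follicular-like cells, and Cd19 at 5755 ± 1569 and 10776 CPM, and doublets of a T cell and a B cell were not tested, since the doublet caller did not work.

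Many germinal-centre-like cells had few antibody counts. Against follicular-like cells the log2 ratios of the median tag counts were -2.66 for CD19, -2.62 for CD1d, -2.91 for IgM and -4.76 for IgD. Under 100 CD19 counts were found on 56.6% and 66.3% of the cells against 0.522% and 1.39%. Another part of the class held more. The upper quartile of CD19 was 392 and 282 counts in the cartridges, beside follicular-like medians of 394 and 320. For CD1d it was 71 and 51 beside 81 and 70, for IgM 719 and 386 beside 871 and 696, and for IgD 778 and 265 beside 1721 and 1416. The low tags did not go with few transcript counts. The median transcript count was 1.41 times that of follicular-like cells in the cartridge with the lower ratio and 1.53 times in the other. This ratio also depends on how much RNA a cell holds and does not measure antibody molecules. It cannot decide whether fewer molecules were captured per cell. The Cd19 transcript was lower by 0.48 on the log2 scale (-0.48 ± 0.08) and the median CD19 tag by -2.48 in the nearer cartridge. These are unlike measures, a fold of summed counts and a ratio of medians. Mean CD19 tag counts were 262 and 207 per germinal-centre-like cell against 455 and 368 per follicular-like cell, a smaller gap. Whether a lower Cd19 transcript accounts for the tag can therefore not be told. One loss of equal size is argued against as the whole cause, because the log2 ratios of the 4 tags spanned 2.14. Those of CD19, CD1d and IgM, though, lay within 0.294 of each other. CD95 was higher (0.55), but at 8.5 against 5.5 counts it lay under the limit of 50 follicular-like counts set for these tags and is not weighed. The transcripts Ighm (-1.79) and Ighd (-3.05) were lower too, so a loss common to the tags may be part of the cause beside lower expression, which these values do not tell apart, and no biological explanation was tested.

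The reporter transcript was higher in germinal-centre-like than in follicular-like cells. Within counting error, more counts per cell are argued against as the whole cause. The thinned share had a lower 95% bound of 2.80% in germinal-centre-like cells, above the upper bound of 2.26% in follicular-like cells. All interval bounds in this paragraph treat each cell as independent, although the cartridge is the replicate. They cover counting error only and may be too narrow. Free reporter RNA, as an equal background in all classes, is argued against by the same bounds, and by a full-depth share with a lower bound of 8.44% in germinal-centre-like cells, above the upper bound of 7.57% over marginal-zone-like and atypical-like cells, whose median counts per cell are higher. The full-depth intervals of B-1-like and plasma-cell-like cells, which have still more counts per cell, overlapped that of germinal-centre-like cells. Scaling is argued against, since the log2 fold change was 1.25 to 1.61 over the other scalings run, with adjusted p values up to 3.3e-04. The thinned shares of germinal-centre-like cells, 3.90% and 5.66%, were above those of marginal-zone-like cells, 2.13% and 2.61%, but their intervals overlapped those of marginal-zone-like (upper bounds 3.20% and 3.96%), atypical-like (3.86% and 5.03%) and plasma-cell-like cells (4.05% and 4.57%), and the differences from these classes were not tested. The thinned plasma-cell-like share is lowered by the immunoglobulin counts that thinning keeps. A higher share of cells of early origin, a stronger reporter promoter in germinal-centre-like cells and tissue of origin may all stay open, untested. So may the numbers of Tom+ and Tom– cells sorted and pooled from each tissue, which can set the share in a class.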

How the results depend on the processing

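All settings but the one that keeps cells without a count of T-cell, macrophage or NK genes were fixed before the data were examined. Of 313 called values of named genes 225 met 2 conditions together. They kept their direction and call under every setting that held their class, and moved by no more than 1 SD of the cartridge folds without either cartridge. The second condition is weak, since this SD comes from the same 2 folds. A value midway between the folds stays within it however far the cartridges differ. Of all 341 values 17 turned under at least 1 setting. Counts of called genes ranged over the settings from 182 to 219 in B-1-like, 143 to 168 in marginal-zone-like, 203 to 214 in germinal-centre-like, 126 to 246 in plasma-cell-like and 136 to 201 in atypical-like cells against follicular-like cells, and from 160 to 189 for B-1-like against marginal-zone-like cells. Genes that turned left aside, leaving out the 5% of cells with most counts ended the call of 32 of 313 called genes, DESeq2 of 21, total counts without TMM of 20, library sizes over held-out genes of 12, no filter on low counts of 9, and only the 2 classes compared of 8 of 312. Again without those that turned, the stricter cell filter ended 9 of 313, doubled resolution 9 of 309, halved resolution 7 of 311, no immunoglobulin genes in the library 7 of 309, no cell filter 12 of 311, the absence of the mixed-type cells 6 of 308, and another seed 2 of 260. With 1 cartridge there is no test, and 17 values without replicate 1 and 19 without replicate 2 moved by more than 1 SD of the cartridge folds. For the reason given above, these counts do not measure agreement between the cartridges. Treating no cell as a doublet changed nothing, since none was called, and the test says nothing of doublets.

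The cartridge was a block, since every class was measured in both. With no replicate block 7 of 313 called genes were no longer past the threshold, none turned, and every count of calls stayed within 1.5 times.

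Without the 5% of cells with most counts plasma-cell-like cells gave 126 called genes in place of 213, and these of the genes named by the rule turned, none of them past the test there: Il2ra (-7.67 ± 3.89, adjusted p = 0.136) and Jun (-0.29) there, Irf7 (0.16) in germinal-centre-like, and Stat1 (0.0545), Tnfrsf13c (0.0906) and Nr4a1 (0.28) in atypical-like cells. Igha in marginal-zone-like cells, not called before, turned to -0.75 and passed (adjusted p = 0.0050), and tdTomato there passed at 0.68. Plasma-cell-like cells hold most counts per cell, and this setting gave 190 and 105 of them in the cartridges in place of 355 and 277 (share 0.576%). The shares of atypical-like, marginal-zone-like and unnamed cells became 2.68%, 7.99% and 52.1%.

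With total counts and no TMM these of the genes named by the rule turned: Igkc in B-1-like (0.0152) and atypical-like cells (0.0695), Irf7 in germinal-centre-like cells (0.0102), Myd88 in atypical-like cells (0.21), and in plasma-cell-like cells Ifitm3 (-0.17), Iglc3 (-0.28), Ccnd2 (-0.30), Jun (-0.40), Itgb1 (-1.25), Irf7 (-1.93) and tdTomato (-1.68). tdTomato passed in B-1-like (0.60) and marginal-zone-like cells (0.64). In plasma-cell-like cells the immunoglobulin genes take most of the total, which lowers every other gene by construction. Of the genes that turned, both Igkc values, Irf7 in germinal-centre-like and Ifitm3 and Ccnd2 in plasma-cell-like cells were not past the test under this setting. Over all called genes, total counts without TMM turned 5 in B-1-like, 17 in germinal-centre-like, 49 in plasma-cell-like and 25 in atypical-like cells. DESeq2 turned 1, 1, 3 and 3 called genes in marginal-zone-like, germinal-centre-like, plasma-cell-like and atypical-like cells, and of the genes named by the rule Iglc2 in marginal-zone-like cells, which was not called with edgeR and passed with DESeq2 (0.15, adjusted p = 0.017). For the reporter in plasma-cell-like cells the call was lost with doubled resolution (0.57), no filter beyond 1 count (0.51), another seed (0.63) and cells without counts of other types (0.61), at adjusted p values of 0.0749 to 0.136. In marginal-zone-like cells it passed with doubled resolution (0.62). In germinal-centre-like cells it stayed called under all settings with a test, at 0.97 to 1.61. Without a cell filter Cd200 turned between B-1-like and marginal-zone-like cells (-0.0841, adjusted p = 0.569). The cause was not tested for the other changes.

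Class shares depend on the clustering. Doubled resolution gave 8.42% B-1-like, 0.153% T-cell-like, 16.1% follicular-like, 5.55% marginal-zone-like and 61.6% unnamed cells. Halved resolution gave 14.1% B-1-like, 2.83% atypical-like, 25.9% follicular-like, 2.78% germinal-centre-like, 7.49% marginal-zone-like, 1.17% plasma-cell-like and 45.7% unnamed. Another seed gave 22.7% follicular-like, 4.89% germinal-centre-like, 6.23% marginal-zone-like, 1.17% plasma-cell-like and 52.1% unnamed, and no atypical-like class, so its values have no counterpart there. No cell filter gave 11.95% B-1-like, 2.86% atypical-like, 22.3% follicular-like, 7.57% marginal-zone-like, 1.32% plasma-cell-like and 49.98% unnamed. At least 100 counts and 30 genes per cell gave 14.5% B-1-like, 1.49% atypical-like, 13.8% follicular-like, 4.81% germinal-centre-like, 6.13% marginal-zone-like, 1.03% plasma-cell-like and 56.2% unnamed. Clustering on all genes gave 10.8% B-1-like, 0.155% T-cell-like, 0.752% atypical-like, 37.7% follicular-like, 5.39% marginal-zone-like and 39.8% unnamed. A memory-like class appeared with doubled resolution (1.65%), with the stricter cell filter (1.92%) and without the 5% of cells with most counts (1.62%), and a macrophage-or-monocyte-like class of 45 cells with clustering on all genes. The cause was not tested.

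Thinning moved the share of cells with a reporter count to 2.28% in B-1-like, 2.23% in atypical-like, 4.78% in germinal-centre-like, 2.37% in marginal-zone-like, 1.93% in plasma-cell-like, 2.16% in unnamed and 2.20% in all cells, since fewer counts per cell hold fewer reporter counts. With an estimated correlation all 10 camera calls were lost, with adjusted p = 0.236 for Toll-like genes in marginal-zone-like cells, 0.982 for B-cell receptor signalling and 0.474 for proliferation in germinal-centre-like cells, 0.182 for immunoglobulin and 0.482 for B-cell receptor signalling, antigen presentation and NF-kB in plasma-cell-like cells, 0.648 for B-cell receptor signalling in atypical-like cells, and 0.432 for B-cell receptor signalling and 0.434 for antigen presentation in B-1-like against marginal-zone-like cells. Within classes Pearson's r between the cartridges was 0.996 in B-1-like, 0.746 in T-cell-like, 0.970 in atypical-like, 0.994 in follicular-like, 0.985 in germinal-centre-like, 0.988 in marginal-zone-like, 0.986 in plasma-cell-like and 0.996 in unnamed cells, against 0.997 in all, with fewer counts per class.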

Other observations

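The splits of B-1-like cells by the CD5 tag and of cells by a reporter count, and the look at unnamed clusters, were chosen after the data were seen.

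B-1-like cells with much CD5 on the surface, a marker that separates B-1a from B-1b cells, were set against those with little. The cells were ranked by the CD5 tag in each cartridge and the outer parts compared, with median tags of 353 and 27.5 counts. Of 294 genes 59 were higher and 60 lower with much CD5 (edgeR, adjusted p under 0.05). Cd5 itself was higher by 4.91 ± 0.29 on the log2 scale, Ccr1 by 1.33 ± 0.05, the inhibitory receptor gene Ctla4 by 1.14 ± 0.08, Slc7a7 by 1.08 ± 0.05, Cd9 by 0.90 ± 0.04, Il18 by 0.65 ± 0.10 and Ccnd2 by 0.54 ± 0.05. Lower were Ighg2b (-1.65 ± 0.11), Ccr6 (-1.01 ± 0.06), Cd36 (-0.99 ± 0.11), Ighg3 (-0.91 ± 0.05) and the macrophage marker Adgre1 (-0.73 ± 0.06). The genes in this paragraph were chosen after their values were seen. Other tags were higher too, with CD43 at 78.5 against 19, CD80 at 181 against 94.5, CD19 at 1139 against 657.5 and IgD at 555 against 200 counts per cell. In cells matched on transcript counts CD80 was at 135.5 against 114.75, and by the ratio of CD5 to CD19 tags it was lower, at 110.25 against 144. IgD was at 397.5 against 216.75 in matched cells and at 306.75 against 298.5 by the ratio. IgM, at 6566 against 5984 in all cells, was lower with much CD5 in matched cells (4417 against 7572) and by the ratio (3219 against 9696).

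Technical explanations of these CD5-related differences were tested. Cells with much CD5 held more counts (median 1800 against 1112), and in cells matched on counts 92 of the 119 called genes were called again in the same direction. T-cell genes stood at 23.9 against 5.04 CPM, and in cells with much CD5 they reached 0.106% of their level in T-cell-like cells. Without cells holding a T-cell count, 86 of the 119 were called again in the same direction. This kept most cells, 1241 of 1301 with much CD5 in cartridge 1. Over the called genes tested again, the median ratio of the new to the first fold was 0.999 there and 1.04 in the matched cells. Ranking by the ratio of CD5 to CD19 tags called 97 of the 119, 91 of them in the same direction. In that ranking the CD19 tag ran the other way, at 697.5 against 1038 counts. This argues against uneven labelling by all antibodies as the whole cause. All these splits draw on the same B-1-like cells, and by the ratio the CD5 tag still stood at 302.75 against 31. The repeated calls are therefore no independent evidence. A difference between B-1a-like and B-1b-like cells may be a hypothesis that stays untested.

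A cluster that met no naming rule held 187 cells with Top2a, Mki67, Lgals1, Spn, Ctla4, Bhlhe41 and Cd5 among its leading genes, that is cell-cycle and B-1 markers together, at a median of 2765 counts per cell. A reporter count was found in 15.5% of its cells (22.2% and 8.86% in the cartridges), and after thinning in 1.85% on average (4 of 108 and 0 of 78 cells). Another unnamed cluster of 885 cells, led by Fas, Pdcd1lg2, Nt5e and Aicda, had a reporter count in 6.73%, and in 5.39 ± 2.55% after thinning, at 104 CPM.

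The hypothesis that cells with a reporter count differ in other transcripts was tested within classes, with 3 matched cells without a count for each cell with one. Apart from tdTomato itself, edgeR called 0 genes in B-1-like, follicular-like, germinal-centre-like, marginal-zone-like or unnamed cells. At an unadjusted p under 0.05 it gave 12 of 286 genes in B-1-like, 16 of 212 in follicular-like, 23 of 251 in germinal-centre-like, 5 of 204 in marginal-zone-like and 38 of 287 in unnamed cells, where chance gives 14.3, 10.6, 12.55, 10.2 and 14.35. The question cannot be decided here, because tdTomato itself did not pass in germinal-centre-like (adjusted p = 0.458) or marginal-zone-like cells (adjusted p = 0.888), and a cell without a count may carry the reporter.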
